A study of Homo sapiens with 8 samples.

How the data were processed

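Total RNA from 8 samples of SKOV3ipL, an ovarian carcinoma cell line, was measured on one-colour Agilent gene expression arrays, 1 array per sample. Per the labels, stable lines had been made with lentiviral constructs, of which sh49 and sh51 carry short hairpin RNAs against CD63 and shNT carries a non-targeting hairpin. The untransduced cells are called parental. Per the labels, cells were seeded on a 10 cm dish 24 hours before RNA was isolated, and 0.2 µg of RNA with a RIN of 10 was labelled with Cy3 using the Agilent Low RNA Input QuickAmp kit. Each of the 4 lines has 2 replicates, described as biological. Whether these came from separate cultures is not stated, so every p-value covers only the spread between these samples. All 8 arrays lie on 1 slide and were read in 1 scan. Each line fills its own column of the slide and each replicate number its own level, so line and slide column cannot be told apart.

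The scanner values are in intensity units per the file headers. Feature Extraction 10.7.3.1 had subtracted the background, removed spatial and multiplicative trends within each array, and replaced signals near background by surrogate values, with no scaling between arrays. The deposited table of processed values is on the log2 scale and holds 1 value per non-control probe. Its 8 columns share 1 maximum and nearly the same quartiles, with medians from 5.74 to 5.76. How the authors normalized these log2 values, corrected their background and combined replicate spots is not stated. Each column of that table correlated best with the scanner values of its own array, with r from 0.985 to 0.989 across probes, and the correlation with the normexp and quantile values was 0.992.

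The comparisons start from the scanner's processed intensity. Control spots were removed from the 62976 spots of an array, which left 58717, and spots marked as population or non-uniformity outliers were left out, 236 to 476 per array. Spots of 1 probe were averaged, and the log2 value had the array's own 75th percentile subtracted, so each level is relative to that percentile. A probe was kept when the scanner marked it well above background, at 13 background standard deviations, on both arrays of at least 1 line. This kept 24611 of 50599 probes. Another 144 probes were left out because outlier marks had removed their spots. Probes were matched to the gene annotation by accession (28174 probes), symbol (2618) or synonym (620). The 19187 others kept the name the array gives them, and accession and symbol named different genes for 29 probes. The brightest probe stood for each gene, giving 18629 genes, of which 14608 carry a current symbol, and 486 tested probes list more than 1 gene.

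Differences between lines were tested with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading. One linear model held the 4 lines as groups with a common spread on 4 residual degrees of freedom, moderated by eBayes with 3.23 prior degrees of freedom, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Tests are two-sided. The comparisons were sh49 with shNT, sh51 with shNT, the mean of both hairpin lines with shNT (called the knockdown), shNT with parental, and sh51 with sh49. Another fit set the 4 hairpin arrays against the 4 control arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays limits the precision of every value.

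The 22 gene lists, with 638 different genes of which 561 were measured, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives except 2. The lists are Wnt/beta-catenin targets, Wnt/beta-catenin pathway components, epithelial markers, mesenchymal markers, EMT (epithelial-mesenchymal transition) transcription factors, extracellular proteases and inhibitors, tetraspanins and partners, lysosome and late endosome, exosome and ESCRT machinery, integrins and focal adhesion, cell cycle, interferon-stimulated genes, NF-kB and inflammatory genes, TGF-beta targets, hypoxia targets, ATF4 and unfolded protein response, cholesterol biosynthesis, NRF2 targets, immediate early and MAPK feedback genes, SKOV3 identity and Mullerian lineage, other cell types, and ribosomal proteins. AKR1C2 and LYZ matched no probe. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with adjusted p over the 22 lists of a comparison. The fry test asks whether the members move one way on balance and does not compare them with other genes.

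CD63 is always given. Other named genes have a symbol in the annotation, passed the test, and lie well above background on both arrays of every line compared. For the knockdown they are the 12 largest rises and 12 largest falls by mean log2 difference among genes changed the same way with both hairpins. The 10 largest each way are taken for shNT with parental and for sh51 with sh49, and the 5 largest each way for each single hairpin, with all of them where fewer passed. Up to 4 members with the smallest p are named per list. Where 1 line was not well above background on either array, up to 5 genes per comparison are given with an at-least fold, taken against the lowest signal that counted as well above background on each of its arrays, or its own signal where that is higher. CTNNB1, CDH1, CDH2, SNAI1, SNAI2, MMP2, MMP9 and TIMP1 are given whatever their values. Some genes that the rule names are not reported here. The rule excludes long non-coding RNAs, and it was settled that this covers MANCR, with 3.23 ± 0.27 in sh51 against sh49 (adjusted p = 0.00159), only after that value had been seen. AXIN2, ELF3 and CCN2 fall outside the rule and were chosen after their values were seen.

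The alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization of the processed signals, median scaling, the authors' processed values, no detection filter, detection on all 8 arrays, the mean of a gene's probes, a trended and robust spread, the replicate number as a block, only the groups compared, adjusted p under 0.01, a change of at least 2-fold, parental cells or both control lines as the control, the cell line as a random block, hairpin comparisons with no control array in common, and each array left out in turn. Where an array is left out, the lone array of its line is assumed to vary like the others. Because under 50% of the probes were detected on every array, the 75th percentile over detected probes was added after seeing the data, and array weights were added because the sh51 replicates differed more than the others.

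The pipeline was tested on simulated data with known changes in 200 genes per run over 10 runs. For the knockdown it recovered 94.8% of changes of 2 on the log2 scale, 31.9% of changes of 1 and 0.896% of changes of 0.5. On average 7.1 unchanged genes per run were called. A list moved by 0.5 was called in 10 of 10 runs, with the preset and with the estimated correlation. The simulated genes varied independently of each other, so this does not cover lists with correlated members. In the data the estimated correlation was 0.0468 for the interferon list and 0.504 for the NF-kB list. For the shared control, 50 simulations of unchanged lines gave the overlap and correlation that 2 comparisons with the same shNT arrays produce when no gene is changed. No sequence was aligned.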

Results

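Transcript levels were measured on 8 one-colour arrays from SKOV3ipL ovarian carcinoma cells, with 2 replicates each of the parental cells, the non-targeting control line shNT, and the CD63 hairpin lines sh49 and sh51. The 75th percentile of the processed signal ran from 492 to 835 intensity units, and 43.5% to 49.8% of the probes were well above background. Levels are log2 signals relative to that percentile. Replicates correlated across genes at 0.981 for sh51 and at 0.992 for the parental, shNT and sh49 lines, and genes are not independent replicates. The replicate difference had a standard deviation of 0.63 in sh51 and of 0.40 to 0.41 in the other lines. Differences are log2 values ± their standard error, each line with n = 2, so the knockdown sets 4 hairpin arrays against 2 shNT arrays.

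CD63, the tetraspanin of late endosomes and exosomes that the hairpins target, was read by 1 probe on chromosome 12 (hg19, 56119667 to 56119950). Its level was 8.09 ± 0.02 (SD, n = 2) in parental cells and 8.30 ± 0.01 (SD, n = 2) in shNT. It was 5.77 ± 0.15 (SD, n = 2) in sh49 and 5.79 ± 0.23 (SD, n = 2) in sh51. CD63 therefore fell by 2.53 ± 0.18 in sh49 (adjusted p = 0.000703) and by 2.51 ± 0.18 in sh51 (adjusted p = 0.00156), to 0.174 and 0.176 of the shNT level. The hairpin lines differed from each other by 0.02 ± 0.18 in CD63, and shNT differed from parental cells by 0.21 ± 0.18, neither past the threshold. All 4 hairpin arrays lay below all 4 control arrays.

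**Figure D1:**
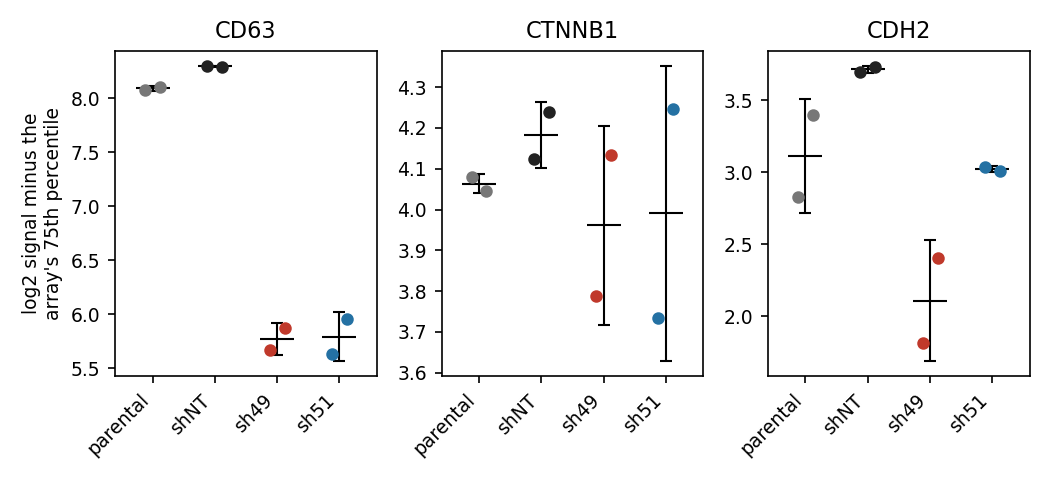
Levels of CD63, CTNNB1 and CDH2 on each array, as log2 signal minus the array's 75th percentile, with points for the 8 arrays and black bars for the mean ± SD of the 2 arrays of a line. CD63 lies near 5.77 and 5.79 in the hairpin lines and at 8.09 and 8.30 in the control lines, whereas the CTNNB1 difference between knockdown and shNT is -0.21.

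The knockdown comparison asks which transcripts differ between the mean of the 2 hairpin lines and shNT, so a gene that moved with 1 hairpin alone can pass too. The largest rises shared by both hairpins included genes of inflammation and immunity. IDO1, the tryptophan-degrading enzyme, rose by 3.84 ± 0.21 (adjusted p = 0.000979), GBP5, an interferon-induced GTPase, by 3.14 ± 0.21, and ALOX5, the lipoxygenase that starts leukotriene synthesis, by 3.14 ± 0.19. The cytokine subunit EBI3 rose by 3.02 ± 0.16, the complement genes C3 and C1S by 2.84 ± 0.21 and 2.52 ± 0.22, and lymphotoxin beta (LTB) by 2.55 ± 0.19. CLDN4, a tight junction claudin, rose by 2.40 ± 0.17 and the adhesion molecule ICAM2 by 2.72 ± 0.29. The largest falls included extracellular matrix genes, EFEMP1 with -3.49 ± 0.25 and the collagens COL5A1 with -2.79 ± 0.21 and COL8A1 with -2.22 ± 0.27. Pregnancy-specific glycoproteins fell as well, PSG6 with -3.57 ± 0.29 and PSG8 with -3.29 ± 0.27, although their probes also list PSG7 and PSG3. The receptors OXTR and S1PR1 fell, with -2.93 ± 0.25 and -2.72 ± 0.29, and so did the TGF-beta family ligand GDF6, with -2.20 ± 0.22. The 12 largest rises were completed by CRYM (3.77), PNMT (2.65) and DOK7 (2.58), and the 12 largest falls by SH3TC1 (-2.78), CD63, SHISA9 (-2.43) and DUSP26 (-2.25). Adjusted p of these 24 genes ran from 0.000979 to 0.00577, and in all 24 the 4 hairpin arrays lay beyond both shNT arrays, in 19 of them beyond the parental arrays as well. The separation from shNT adds little, since it held for all 240 genes that passed the same way with both hairpins. Another probe of SH3TC1 gave 0.37 (adjusted p = 0.65).

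In the knockdown 856 genes changed, 544 up and 312 down, and all 4 hairpin arrays lay beyond both shNT arrays in 759 of them. Of the 856 genes 240 also passed the same way with each hairpin, 491 with sh49 alone, 104 with sh51 alone and 21 with neither, and 373 differed between the hairpin lines. With parental cells as the control the calls ended for DOK7 (0.67), EFEMP1 (-0.96), S1PR1 (-1.09), SHISA9 (-0.46), DUSP26 (-0.70) and COL8A1 (-0.51), the last also without shNT replicate 2 (-1.98), and CRYM (2.48), ALOX5 (1.87) and GDF6 (-1.28) were smaller, as were ALOX5 (1.83), GBP5 (1.73) and EBI3 (1.81) with normexp background and SH3TC1 (-1.21) with the mean of a gene's probes. The count of 856 became 459 and 558 without shNT replicates 1 and 2, where more genes fell than rose (180 up and 279 down, 202 up and 356 down), 546 and 556 without parental replicates 1 and 2, 494 without sh49 replicate 1, 1313 without sh51 replicate 2, 177 with no detection filter, 295 at adjusted p under 0.01 and 1339 with both control lines as the control.

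Interferon-stimulated genes rose together in the knockdown. Of 31 measured members 8 rose, none fell and 23 did not pass, and 17 rose when adjusted over the list alone. IFITM1, which blocks virus entry, rose by 2.06 ± 0.19, the antiviral GTPase MX1 by 1.28 ± 0.14, the RNA sensor IFIH1 by 1.33 ± 0.19 and IFI44 by 1.32 ± 0.20. IFITM1 and MX1 passed with each hairpin, whereas IFIH1 passed in sh49 (1.55) and not in sh51 (1.11, adjusted p = 0.0537), and IFI44 in sh51 (1.88) and not in sh49 (0.76, adjusted p = 0.0973). The hairpin lines differed in IFI44 (1.12, adjusted p = 0.0298) and not past the threshold in IFIH1 (adjusted p = 0.302). The list's median was 0.52 (adjusted p = 3.62e-12), with 17 of 31 members higher on all 4 hairpin arrays than on both shNT arrays, and its call was lost with an estimated correlation (adjusted p = 0.123 with an estimated correlation). Its fry adjusted p was 0.00597. In shNT against parental cells the same list had a median of 0.09 and did not pass (adjusted p = 0.555). NF-kB and inflammatory genes rose too, with 7 of 24 measured members up, none down and 17 not past, and 10 up when adjusted over the list alone. The chemokine CCL2 rose by 1.54 ± 0.19, the acute phase protein SAA1 by 1.56 ± 0.23, the siderophore-binding LCN2 by 1.30 ± 0.22 and the apoptosis inhibitor BIRC3 by 1.70 ± 0.29. SAA1 and LCN2 passed with each hairpin, CCL2 and BIRC3 only in sh49 (1.97 and 2.10, against 1.11 and 1.29 in sh51), without a difference past the threshold between the lines (adjusted p = 0.0633 and 0.201). The list's median was 0.81 (adjusted p = 8.48e-10, and adjusted p = 0.447 with an estimated correlation), 11 of 24 members were higher on all 4 hairpin arrays, and fry did not call it (adjusted p = 0.0784). In the list of other cell types, which holds leukocyte, endothelial, mesothelial and fibroblast markers, 10 of 23 genes were measured, none rose, and the mesothelial gene LRRN4 fell by 1.06 ± 0.20 on the log2 scale, with -0.80 in sh49 (adjusted p = 0.088) and -1.32 in sh51 (adjusted p = 0.0333), and with 0.239 as the adjusted p between the lines. Its median was -0.10 and the list did not pass (adjusted p = 0.282). Of 22 alternatives the calls held under 22 for IFITM1, 21 for MX1, 20 for IFI44, CCL2 and SAA1, 19 for IFIH1, 18 for LCN2 and BIRC3 and 15 for LRRN4. No detection filter ended all but that of IFITM1. Leaving out shNT replicate 1 ended those of IFIH1 (1.44), CCL2 (1.33), SAA1 (1.26), LCN2 (1.26), BIRC3 (1.81) and LRRN4. Leaving out shNT replicate 2 ended those of IFIH1 (1.22), IFI44 (1.14), LCN2 (1.33), BIRC3 (1.58) and LRRN4. Parental cells as the control ended those of BIRC3 (1.17) and LRRN4 (-0.70), with CCL2 at 2.40 there and MX1 at 0.75 and IFI44 at 0.86 with normexp background.

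**Figure D2:**
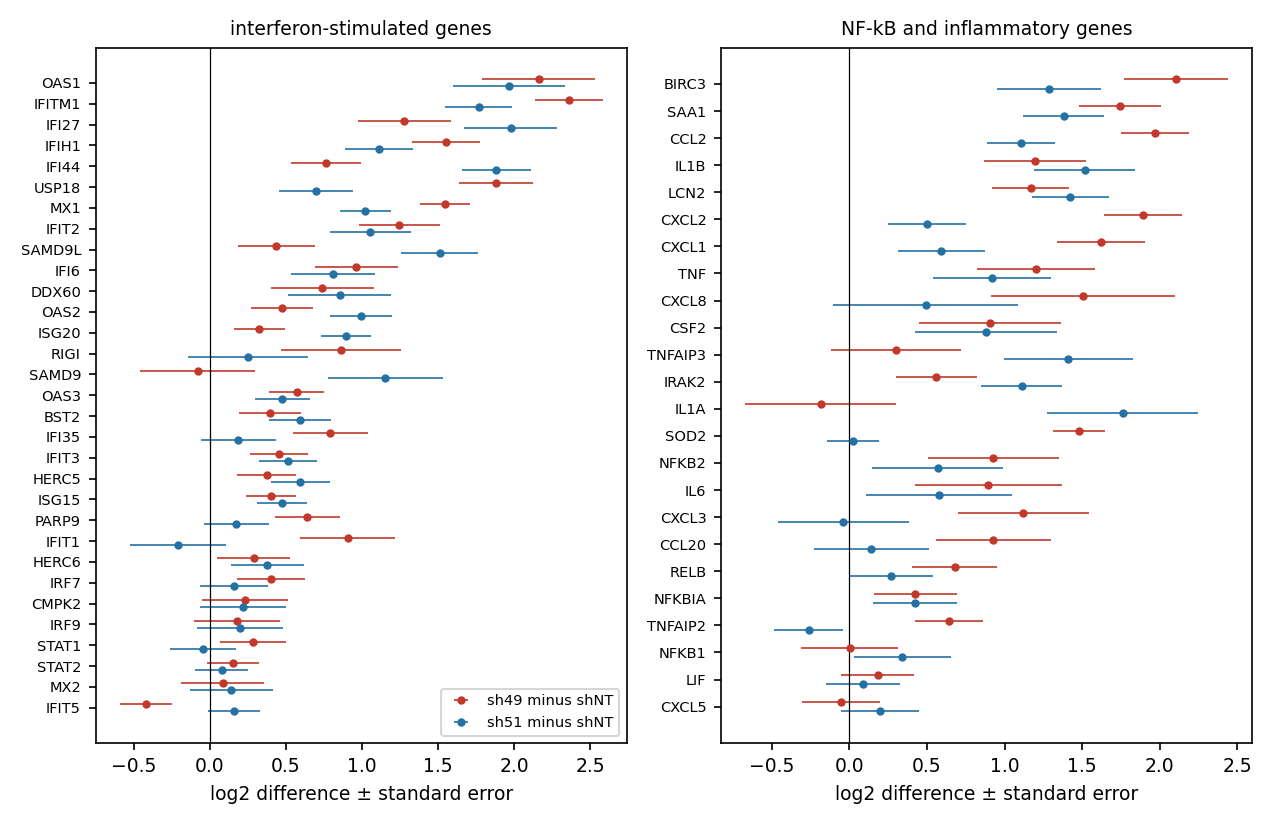
Log2 difference from shNT ± standard error of each measured interferon-stimulated and NF-kB gene, with sh49 in red and sh51 in blue. The medians are 0.47 in sh49 and 0.59 in sh51 for interferon-stimulated genes, and 0.93 and 0.57 for NF-kB genes.

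The series title names beta-catenin, and its transcript CTNNB1 did not pass in the knockdown, with -0.21 ± 0.19 (adjusted p = 0.692) and a 95% interval from -0.66 to 0.24. The arrays read RNA, so beta-catenin protein was not measured. In simulated data 31.9% of changes of 1 and 0.896% of changes of 0.5 were recovered, so genes that did not pass may have changed. Among 30 measured Wnt/beta-catenin targets 1 rose, 4 fell and 25 did not pass, and 2 rose and 4 fell when adjusted over the list alone. The receptor EPHB2 fell by 0.89 ± 0.14, the transcription factor SP5 by 1.02 ± 0.16 and TCF7, a partner of beta-catenin on DNA, by 0.71 ± 0.14. AXIN2, a feedback inhibitor of the pathway, fell by 0.81 ± 0.17 and the protease MMP7 rose by 1.86 ± 0.34. None of these 5 passed with both hairpins. Another probe of TCF7 did not pass in the knockdown (-0.49, adjusted p = 0.167). Of the other EPHB2 probes, 1 passed there (-0.90, adjusted p = 0.0183) and 1 did not (-0.69, adjusted p = 0.366). EPHB2 fell in sh49 alone, by 1.78, and the hairpin lines differed in it by 1.78 (adjusted p = 0.00186). TCF7 (-0.96 and -0.46) and MMP7 (2.64 and 1.08) passed in sh49 and not in sh51, without a difference past the threshold between the lines (adjusted p = 0.115 and 0.0621), SP5 passed in sh51 and not in sh49 (-0.68 and -1.36, adjusted p = 0.0774 between the lines), and AXIN2 in neither (-0.65 and -0.96). The list as a whole did not pass, with a median of -0.16 (adjusted p = 0.112), 7 members lower and 2 higher on all 4 hairpin arrays. Its median was -0.33 in sh49, where 4 members rose and 2 fell, and -0.21 in sh51, where 0 rose and 1 fell. Of 39 measured Wnt/beta-catenin pathway components 1 rose, 2 fell and 36 did not pass, with 1 up and 3 down when adjusted over the list alone. The receptor FZD4 fell by 0.87 ± 0.15 and the ligand WNT5A by 1.41 ± 0.25, the ligand WNT10A rose by 1.17 ± 0.23, and the inhibitor SFRP1 was at -0.66 ± 0.15 without passing. FZD4 (-0.94 and -0.79) and WNT5A (-1.51 and -1.31) passed in sh49 and not in sh51 (adjusted p = 0.66 and 0.753 between the lines), WNT10A in sh51 alone (0.57 and 1.76), with a difference of 1.19 between the lines (adjusted p = 0.0394). The list's median was -0.02 (adjusted p = 0.247). The target list passed without sh49 replicate 2 (median -0.25, adjusted p = 0.0319, in a range of 0.0319 to 0.481 over its alternatives) and its median was 0.05 with no detection filter, while of 22 alternatives the EPHB2 call held under 16, SP5 under 18, TCF7 under 11 and MMP7 under 14. The calls held under 15 for FZD4, 13 for WNT5A and 16 for WNT10A, with EPHB2 at -0.65 with normexp background and -0.68 with the authors' values, FZD4 at -0.53 and WNT5A at -0.55 with parental cells as the control, none past, and with parental cells MMP7 at 1.57, not past, and WNT10A at 1.75.

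TGF-beta targets fell in the knockdown, with 5 of 23 measured members down, none up and 18 not past, and 8 down when adjusted over the list alone. INHBA, an activin subunit, fell by 2.63 ± 0.28, TPM1 by 0.89 ± 0.15, PMEPA1 by 0.87 ± 0.15 and the matricellular CCN2 by 1.33 ± 0.27. All 4 fell in sh49 (-4.30, -1.12, -1.76 and -2.01) and none passed in sh51 (-0.95, -0.66, 0.01 and -0.65), and the hairpin lines differed in INHBA (3.35), PMEPA1 (1.77) and CCN2 (1.36) but not past the threshold in TPM1 (0.46, adjusted p = 0.163). Another probe of PMEPA1 did not pass in the knockdown (-0.68, adjusted p = 0.204). Over the list 5 members fell in sh49 and 1 in sh51. The median was -0.28 (adjusted p = 0.0002, and adjusted p = 0.447 with an estimated correlation), and fry did not call the list (adjusted p = 0.102). Epithelial markers had 4 of 26 measured members up, 1 down and 21 not past, and 7 up and 1 down when adjusted over the list alone. Beside CLDN4, the tight junction gene TJP3 rose by 1.98 ± 0.27, the desmosomal PKP2 by 1.28 ± 0.19 and the epithelial transcription factor ELF3 by 1.06 ± 0.21, while the splicing factor ESRP2 fell by 0.71 ± 0.14. CLDN4 passed with each hairpin. TJP3 (3.38 and 0.59) and ELF3 (1.85 and 0.27) rose in sh49 alone, with differences of -2.79 and -1.58 between the lines (adjusted p = 0.0035 and 0.0105), PKP2 in sh51 alone (0.80 and 1.76, difference 0.96), and ESRP2 fell in sh49 and did not pass in sh51 (-0.94 and -0.48, adjusted p = 0.143 between the lines). Their median was 0.20 (adjusted p = 0.00795, and adjusted p = 0.35 with an estimated correlation), with a fry adjusted p of 0.0213. Mesenchymal markers had 3 of 19 measured members down, 2 up and 14 not past, and 7 down and 2 up when adjusted over the list alone. COL5A1 and the matrix protein SPARC (-1.39 ± 0.18) fell, as did N-cadherin (CDH2), with -1.15 ± 0.23, whereas COL6A1 (1.02 ± 0.14) and smooth muscle actin ACTA2 (1.32 ± 0.22) rose. COL5A1 and SPARC fell with each hairpin, CDH2 in sh49 and not past in sh51 (-1.61 and -0.69, adjusted p = 0.0854 between the lines). In sh49 another COL5A1 probe gave -2.05 (adjusted p = 0.0160), and a further one -0.83 without passing (adjusted p = 0.201). COL6A1 (1.501 and 0.53) and ACTA2 (2.26 and 0.39) rose in sh49 alone and differed between the lines, by -0.97 and -1.87. Their median was -0.71 (adjusted p = 0.013, and adjusted p = 0.481 with an estimated correlation), and fry did not call the list (adjusted p = 0.137). Of 12 measured EMT transcription factors only TCF4 passed, with -2.11 ± 0.23 and with each hairpin, and the list did not (adjusted p = 0.543), its median being 0.01 while its mean of -0.20 and its test pointed down. The calls held under 22 of 22 alternatives for INHBA and CLDN4, 20 for SPARC and COL6A1, 19 for PKP2, 16 for TPM1, 14 for PMEPA1 and 13 for ESRP2. They held under 16 of 21 for TJP3 and ACTA2, which ended with parental cells as the control (0.72 and 0.23) and with normexp background (0.42 and 0.49). With the authors' processed values the TJP3 call ended too (1.01, adjusted p = 0.0591), while ACTA2 passed at 0.78. CCN2, ELF3 and AXIN2 were not run under the alternatives. With parental cells ESRP2 stood at -0.37, not past, and TCF4 at -1.32, and with normexp background TCF4 at -1.24 and PKP2 at 0.85.

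Among the other genes tied to invasion, SNAI1 (0.08 ± 0.16), SNAI2 (-0.94 ± 0.36, adjusted p = 0.252), MMP9 (0.00 ± 0.16) and TIMP1 (0.19 ± 0.17) did not pass in the knockdown. For SNAI2 this mean joins unlike hairpin lines, with levels of -0.85 in sh49 and 1.80 in sh51 against 1.41 in shNT. The hairpin lines differed in SNAI2 by 2.65 (adjusted p = 0.0124). CDH1 was well above background on 0 of 8 arrays, and the probes of MMP2 on at most 1, so neither has a value here. Extracellular proteases and inhibitors had 3 of 26 measured members up and 3 down, 7 and 4 when adjusted over the list alone. The collagenase MMP1 rose by 1.04 ± 0.18, and the aggrecanases ADAMTS1 (-1.42 ± 0.20) and ADAMTS5 (-1.80 ± 0.30) fell. ADAMTS5 passed with each hairpin, while MMP1 (1.23 and 0.85) and ADAMTS1 (-1.72 and -1.11) passed in sh49 and not in sh51 (adjusted p = 0.316 and 0.165 between the lines). With parental cells as the control none of the 3 passed (MMP1 0.72, ADAMTS1 -0.87 and ADAMTS5 -0.62). Of 22 alternatives the MMP1 call held under 16 and those of ADAMTS1 and ADAMTS5 under 18, MMP1 and ADAMTS1 being lost without either shNT array and ADAMTS5 without shNT replicate 1 (-1.46). The list's median was 0.24 (adjusted p = 0.0826). The call of the TGF-beta list ended without shNT replicate 2 (median -0.21, against -0.46 without shNT replicate 1), that of the epithelial list without sh51 replicate 2 (0.36, in a range from 0.13 with median scaling to 0.47 with parental cells as the control), and that of the mesenchymal list with parental cells (-0.41) or both lines (-0.37) as the control and without shNT replicate 2 (-0.48), its median being -0.20 with normexp background and -0.15 with no detection filter. The CDH2 call ended under 7 of 22 alternatives, among them no detection filter, parental cells as the control (-0.55), array weights, and the fits without shNT replicate 1 (-1.17), shNT replicate 2 (-1.13), sh49 replicate 1 (-1.0002) or sh51 replicate 1 (-1.16).

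In the cell cycle list no member of 36 passed, also when adjusted over the list alone, yet the list was lower as a whole, with a median of -0.21 (adjusted p = 0.00514, and adjusted p = 0.35 with an estimated correlation) and a fry adjusted p of 0.0472. The nucleotide synthesis genes TYMS and RRM2 stood at -0.40 ± 0.14 and -0.60 ± 0.24. Cholesterol biosynthesis had no member of 24 past over all genes, and 1 up and 3 down when adjusted over the list alone, with the mevalonate kinase MVK at -0.70 ± 0.16 and the isomerase EBP at -0.76 ± 0.21. Its median was -0.33 (adjusted p = 0.00356, and adjusted p = 0.447 with an estimated correlation), and fry did not call it (adjusted p = 0.119). Against parental cells this median was 0.23, so the direction turned, and the call ended with both lines as the control (-0.01) and without shNT replicate 2 (-0.25). The call of the cell cycle list ended without shNT replicate 1 (-0.16).

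The remaining lists did not pass as a whole in the knockdown. Of 24 alternatives, hypoxia targets passed under 9, SKOV3 identity and Mullerian lineage genes under 4, and lysosome and late endosome genes under 3. The other lists of this paragraph passed under at most 1. Tetraspanins and partners had 1 of 22 measured members up, TSPAN1 with 1.42 ± 0.21 (1.58 in sh49, and 1.25 in sh51 without passing), and a median of 0.16 (adjusted p = 0.229). When adjusted over the list alone 2 rose and 3 fell. Lysosome and late endosome genes, the compartment where CD63 resides, had 1 of 37 up, the protease CTSD with 1.01 ± 0.18 (1.32 in sh49, and 0.69 in sh51 without passing), and a median of 0.05 (adjusted p = 0.154), though fry called them (adjusted p = 0.0472). None of 34 exosome and ESCRT genes passed, with a median of -0.01, a mean of 0.01 and a test pointing down (adjusted p = 0.817), nor did any of 30 integrin and focal adhesion genes (median 0.05, adjusted p = 0.229) or 26 hypoxia targets (median -0.14, adjusted p = 0.0607). ATF4 and unfolded protein response genes had 1 of 28 up and 1 down, the cystine transporter SLC7A11 with 1.20 ± 0.20 and TRIB3 with -0.85 ± 0.15, around a median of 0.04 (adjusted p = 0.915). SLC7A11 rose in sh51 alone (0.08 and 2.32, a difference of 2.23 between the lines), and TRIB3 passed in sh49 (-0.87) and not in sh51 (-0.83). NRF2 targets had 3 of 21 up, 5 up and 1 down when adjusted over the list alone, and a median of 0.09 (adjusted p = 0.108). Besides SLC7A11 these were the aldo-keto reductases AKR1C3 with 1.28 ± 0.16 and AKR1C1 with 0.89 ± 0.19. AKR1C3 passed with each hairpin and AKR1C1 with neither (0.89 and 0.90). Another probe of AKR1C1 did not pass in the knockdown (0.72, adjusted p = 0.116). Immediate early and MAPK feedback genes had 1 of 26 up, SPRY4 with 1.29 ± 0.23, and 1 down, EPHA4 with -1.76 ± 0.26, around a median of 0.12 (adjusted p = 0.225). EPHA4 passed with each hairpin and SPRY4 in sh51 (1.57) and not in sh49 (1.02). SKOV3 identity and Mullerian lineage genes had 1 of 22 up, CLDN4, with 6 up and 2 down when adjusted over the list alone and a median of 0.17 (adjusted p = 0.10). The lineage factors WT1 (-0.82 ± 0.18) and EMX2 (-0.85 ± 0.19) did not pass over all genes. TSPAN1, CTSD, TRIB3 and SPRY4 did not differ past the threshold between the hairpin lines (lowest adjusted p = 0.129). No ribosomal protein gene of 34 passed, with a median of 0.02 and adjusted p = 0.975, its test pointing down. With parental cells as the control SLC7A11 stood at -0.74 and AKR1C1 at -0.38, neither past, so both directions turned, and AKR1C3 (0.44), TRIB3 (-0.10), SPRY4 (0.73) and CTSD (0.76) did not pass. Of 22 alternatives the AKR1C1 call held under 6 only, being lost whichever array was left out. The calls held under 19 for AKR1C3, 18 for TSPAN1 and EPHA4, 17 for SPRY4, 15 for SLC7A11, 14 for CTSD and 13 for TRIB3, with SLC7A11 at 0.23, AKR1C1 at 0.26 and TRIB3 at -0.47 with both lines as the control.

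Each hairpin was also compared with shNT alone. In sh49 the stress cytokine GDF15 rose by 5.54 ± 0.42 (adjusted p = 0.000905), IDO1 by 5.30 ± 0.24, CRYM by 5.15 ± 0.37, the guanine nucleotide exchange factor VAV3 by 4.70 ± 0.39 and C3 by 4.01 ± 0.24. INHBA fell by 4.30 ± 0.32, OXTR by 3.68 ± 0.29, S1PR1 by 3.41 ± 0.33, the homeobox gene HOXC9 by 3.25 ± 0.19 and the chorionic gonadotropin subunit CGB3 by 3.23 ± 0.35, whose probe also lists CGB1, CGB5 and CGB7. LRG1 was at least 15.1-fold and PTX3 at least 11.3-fold higher in sh49, ANK3 at least 9.74-fold higher, and AMTN and NOG at least 9.90-fold and 8.97-fold lower. AMTN was well above background on only 1 of 2 parental arrays, and sh49 did not differ from parental cells in it past the threshold (adjusted p = 0.197). The lists past the threshold were interferon-stimulated genes (7 up, median 0.47), NF-kB genes (7 up, 0.93), TGF-beta targets (5 down, -0.51), the cell cycle (-0.24) and cholesterol biosynthesis (1 up and 2 down, -0.38), with adjusted p from 1.09e-07 to 0.0143, and none passed with an estimated correlation (lowest adjusted p = 0.278 with an estimated correlation). Of these lists fry called interferon-stimulated genes (fry adjusted p = 0.0110) and the cell cycle (fry adjusted p = 0.0314). It did not call the others (fry adjusted p from 0.0717 to 0.0895). In sh49 1496 genes changed, 952 up and 544 down. In all of them both sh49 arrays lay beyond both shNT arrays, which nearly follows from a call with 2 arrays per line and adds no support. The count became 702 (374 up and 328 down) without shNT replicate 1, 911 (465 and 446) without shNT replicate 2 and 660 (497 and 163) without sh49 replicate 1, 447 with no detection filter and 583 at adjusted p under 0.01. Median scaling moved the median of all genes by -0.13 and the share of rises from 63.6% to 50.8%.

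In sh51 CLDN4 rose by 2.97 ± 0.20 (adjusted p = 0.00137), LTB by 2.96 ± 0.22, SUSD2 by 2.93 ± 0.44, ICAM2 by 2.92 ± 0.34 and GBP5 by 2.76 ± 0.24. PSG6 fell by 4.95 ± 0.34, PSG8 by 4.80 ± 0.32, EFEMP1 by 3.98 ± 0.29, the endothelial GTPase regulator RASIP1 by 3.95 ± 0.21 and the transcription factor RUNX3 by 3.21 ± 0.25. The vitamin D hydroxylase CYP24A1 was at least 23.9-fold lower in sh51, PSG5 at least 19.6-fold and PSG2 at least 13.0-fold lower, and FAM107A at least 13.5-fold higher. IGFBP5 was at least 11.0-fold lower in sh51 than in shNT, but shNT was the only line where it was well above background, parental cells included. Against parental cells SUSD2 (0.97, adjusted p = 0.418) and EFEMP1 (-1.45, adjusted p = 0.0624) did not pass in sh51. The lists past the threshold were interferon-stimulated genes (7 up, median 0.59), NF-kB genes (2 up, 0.57), epithelial markers (2 up, 0.25), integrins and focal adhesion (1 up, 0.24), mesenchymal markers (3 down, -0.69), TGF-beta targets (1 down, -0.13), immediate early genes (1 up and 1 down, 0.32) and cholesterol biosynthesis (-0.26). Their adjusted p ran from 2.01e-11 to 0.0137, and none passed with an estimated correlation (lowest adjusted p = 0.138 with an estimated correlation). Of these lists fry called interferon-stimulated genes (fry adjusted p = 0.0119) and epithelial markers (fry adjusted p = 0.0229). It did not call the others (fry adjusted p from 0.150 to 0.221). In sh51 469 genes changed, 226 up and 243 down, with both sh51 arrays beyond both shNT arrays in all of them, which again nearly follows from the call. The model used 1 common spread, although the replicate difference had a standard deviation of 0.63 in sh51 and of 0.40 to 0.41 in the other lines. This can make p-values too small in sh51 and too large between the other lines. The split depended on single arrays, with 94 up and 239 down without shNT replicate 1, 92 and 318 without shNT replicate 2 and 615 and 277 without sh51 replicate 2, so the share of rises ran from 22.4% to 68.9%. The count became 290 without either parental array, 302 without sh49 replicate 1 and 892 without sh51 replicate 2, and 56 with no detection filter, 136 at adjusted p under 0.01, 137 with only the groups compared and 279 with array weights. The SUSD2 call ended with no detection filter and without shNT replicate 1 (3.05), shNT replicate 2 (2.81) or either sh49 array (2.93), and the ICAM2 call with no detection filter (2.92), while with normexp background SUSD2 stood at 1.90 and GBP5 at 1.45.

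Both hairpins changed 240 genes the same way, 141 up and 99 down, and 18 in opposite ways. Lists drawn independently would share 18.6, so the number is 12.9 times as large. In 50 simulations of unchanged lines with shared shNT arrays 0 genes were shared. With no gene changed hardly any can be called, so this 0 cannot tell how many of the 240 the shared arrays gave. With no control array in common the hairpins shared 141 genes (9.21 times the 15.3 of independent lists) or 171 genes (9.45 times 18.1), with 36 or 40 in opposite ways. These shared genes held 110 or 163 of the 240. Across genes, which are not independent replicates, the effects of the hairpins correlated at r = 0.424 (Spearman 0.339), against 0.499 (0.470) simulated for unchanged lines that share the shNT arrays. Their covariance was 0.138 against 0.0426 simulated. With no control array in common r was 0.226 and 0.225. Without shNT replicates 1 and 2 it was 0.592 and 0.684, and unchanged lines that share a single shNT array were not simulated. Of the 240 genes 61 also differed between the hairpin lines, and 96 genes, 58 up and 38 down, changed the same way against both control lines. The count of 240 became 150 and 151 without parental replicates 1 and 2, 111 and 145 without sh49 replicates 1 and 2, 25 with no detection filter, 62 at adjusted p under 0.01 and 90 with only the groups compared. The count of 96 became 46 and 27 without parental replicates 1 and 2, 28 and 30 without shNT replicates 1 and 2, 42 and 50 without sh49 replicates 1 and 2, 8 with no detection filter, 21 at adjusted p under 0.01, 3 with only the groups compared and 61 with array weights.

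**Figure D3:**
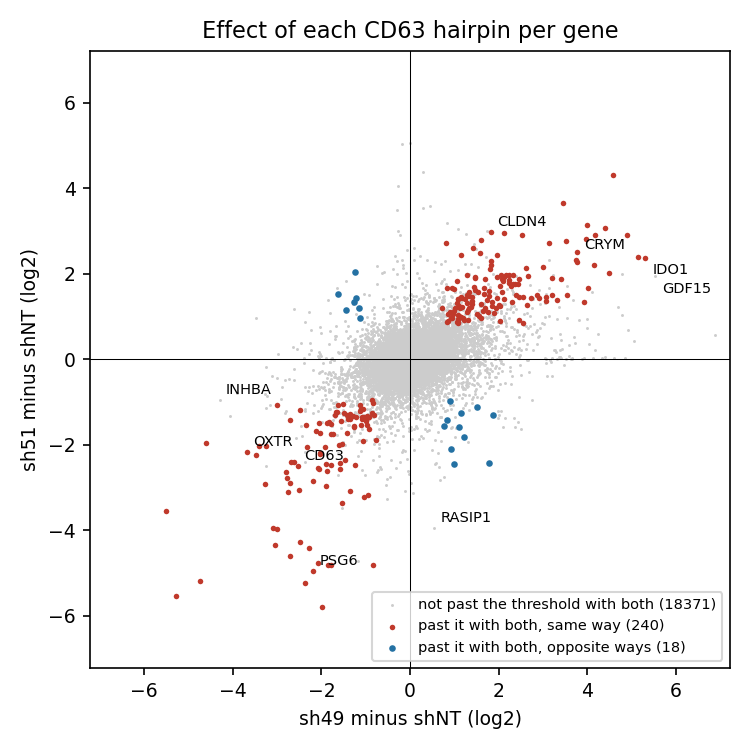
Log2 difference from shNT of each gene in sh49 (x axis) and sh51 (y axis), with 240 genes changed the same way with both hairpins in red, 18 changed in opposite ways in blue and the 18371 others in grey. Correlation across genes is 0.424, and CD63 lies at -2.53 and -2.51.

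The comparison of sh51 with sh49 asks how far the hairpin lines depart from each other, CD63 itself differing by 0.02 between them. INHBA was 3.35 ± 0.32 higher in sh51 than in sh49 (adjusted p = 0.00237), HOXC9 3.08 ± 0.19, the small GTPase RAB8B 3.11 ± 0.34, the podosome scaffold SH3PXD2A 2.80 ± 0.24 and the complement inhibitor CD59 2.77 ± 0.35. SNAI2, a transcription factor of epithelial-mesenchymal transition, was 2.65 ± 0.42 higher, having fallen by 2.27 ± 0.42 in sh49 and stood at 0.38 ± 0.42 in sh51. RASIP1 was lower in sh51, with -4.50 ± 0.21, as were GDF15 (-3.59 ± 0.42), VAV3 (-3.47 ± 0.39), the endothelin EDN2 (-3.17 ± 0.31) and PSG8 (-3.02 ± 0.32). The 10 largest each way also held SPANXA1 (3.81, its probe listing SPANXA2 and SPANXC), FAM25A (2.66, its probe listing FAM25C and FAM25G), RGCC (2.63) and MDFI (2.51), and CCDC3 (-3.43), TMEM37 (-3.27), NEURL3 (-3.27), TMEM130 (-3.18) and CNRIP1 (-3.01). CCDC3, TMEM130 and CNRIP1 rose in sh49 (0.99, 1.86 and 0.92) and fell in sh51 (-2.44, -1.31 and -2.09), and FAM25A did the reverse (-1.22 and 1.44). ARSL was at least 11.5-fold, CAMP and CXADRP3 at least 7.52-fold and F2 at least 7.20-fold lower in sh51, and FAM107A at least 9.99-fold higher.

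Integrins and focal adhesion genes were higher in sh51 than in sh49, with 7 of 30 measured members up, 1 down and 22 not past. The laminin chains LAMA3 and LAMB3 were higher by 1.40 ± 0.21 and 1.37 ± 0.18, and the tensin TNS1 by 1.74 ± 0.19, but another probe of LAMA3 gave -0.21 (adjusted p = 0.726). The median was 0.33 (adjusted p = 0.00487, and adjusted p = 0.556 with an estimated correlation) with a fry adjusted p of 0.0485. Immediate early and MAPK feedback genes had 2 of 26 up, the phosphatase DUSP4 with 1.28 ± 0.21 and PHLDA1 with 0.88 ± 0.16, and a median of 0.35 (adjusted p = 0.0269, and adjusted p = 0.734 with an estimated correlation), and fry did not call them (adjusted p = 0.203). Interferon-stimulated genes had a median of -0.01 between the hairpin lines (adjusted p = 0.979, test pointing up). In this comparison 1394 genes differed, 535 higher and 859 lower in sh51. The 2 arrays of each line lay apart in all of them, which nearly follows from the call. Median scaling moved the median of all genes by 0.11 and the share of rises from 38.4% to 49.9%. Both list calls ended without sh51 replicate 2 (medians 0.34 and 0.43), and the calls of CD59, SNAI2 and RGCC ended with only the groups compared, that of SNAI2 also with no detection filter, and NEURL3 stood at -2.06 with normexp background. The count of 1394 became 842 and 869 without parental replicates 1 and 2, 904 and 854 without shNT replicates 1 and 2, 574 without sh49 replicate 1 (136 higher and 438 lower), 1601 without sh51 replicate 2, where more were higher than lower (850 and 751), 377 with no detection filter, 411 with only the groups compared and 446 at adjusted p under 0.01.

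Comparing shNT with parental cells shows what accompanies the non-targeting construct, together with the making of the line and its slide column. ADIRF, an adipogenesis regulator, fell by 2.74 ± 0.21 in shNT (adjusted p = 0.0207). The growth factor binding protein IGFBP5 was at least 11.5-fold higher in shNT than in parental cells, the cancer-testis antigens CSAG1 and MAGEC1 at least 4.56-fold and 1.78-fold higher, and the kinase ALPK2 at least 1.94-fold higher, all with adjusted p = 0.0207. Those 5 genes were all that passed. Of 18629 genes 908 had an unadjusted p under 0.05, no more than that threshold gives when no gene differs. That count is therefore no sign of further differences. Single genes may still differ, since MAGEC2 stood at 3.24 without passing (adjusted p = 0.0648). Among knockdown falls, SHISA9 (-2.43) and COL8A1 (-2.22) were at -0.46 and -0.51 against parental cells, so shNT lay above parental cells in them. Other falls held there, such as PSG6, whose call held under 22 of 22 alternatives. Cholesterol biosynthesis was higher in shNT, with a median of 0.51 (adjusted p = 2.02e-16, and adjusted p = 0.245 with an estimated correlation). None of its 24 members passed over all genes and 2 rose when adjusted over the list alone, with HSD17B7 at 0.86 ± 0.18 and INSIG1 at 0.85 ± 0.26, and fry did not call it (adjusted p = 0.141). Epithelial markers (median 0.16) and NRF2 targets (median -0.13) passed with adjusted p = 0.00632 each, and adjusted p = 0.266 with an estimated correlation for both, and neither passed with fry (adjusted p = 0.309 and 0.141). NF-kB genes (median -0.08, adjusted p = 0.83, test pointing up) and Wnt/beta-catenin targets (median 0.00, mean -0.02, adjusted p = 0.90, test pointing up) did not pass. The ADIRF call ended with no detection filter, with only the groups compared and without either sh49 array (-2.74 in each), the epithelial call without shNT replicate 2 (0.13), and the NRF2 call without parental replicate 2 (-0.11) or shNT replicate 1 (-0.20). The count of 5 became 153 and 65 without parental replicates 1 and 2, mostly falls (142 and 58), 125 and 199 without shNT replicates 1 and 2, mostly rises (116 and 187), 0 without either sh49 array, 3 and 10 without sh51 replicates 1 and 2, and ran from 0 to 40 under the other alternatives.

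Setting all 4 hairpin arrays against all 4 control arrays asks which genes separate the hairpin arrays from the control arrays. The fit counts the 2 arrays of a line as independent, although each side holds only 2 lines. Its p-values therefore do not cover the spread between lines. In this fit 353 genes changed, 247 up and 106 down, and 2859 had an unadjusted p under 0.05. With the cell line as a random block the count was 228, and with the replicate number as a block 233. It became 116 and 84 without parental replicates 1 and 2, 75 and 84 without shNT replicates 1 and 2, 143 and 104 without sh49 replicates 1 and 2, 89 with no detection filter, 68 at adjusted p under 0.01, 225 with at least a 2-fold change and 4774 with array weights, which gave sh49 replicate 2 a weight of 6.72.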

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

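The tests of unequal CD63 levels and of slide position were chosen only after the result was seen. The results below stand out because a test of the difference between the hairpin lines passed, and each value is sh51 minus sh49 on the log2 scale. This held for 30 of the 75 named genes whose effects were compared.

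Several genes of inflammation and complement moved further in sh49 than in sh51, namely IDO1 (-2.92), C3 (-2.33), C1S (-2.04), EBI3 (-1.48) and ALOX5 (-1.27), whereas IFI44 rose further in sh51 (1.12). GDF15 (-3.59), VAV3 (-3.47), CRYM (-2.76) and PNMT (-1.53) were also higher in sh49. Among epithelial and mesenchymal genes, CLDN4 (1.14), PKP2 (0.96) and SNAI2 (2.65) were higher in sh51, and TJP3 (-2.79), ACTA2 (-1.87), COL8A1 (-1.74) and COL6A1 (-0.97) were lower. The Wnt genes EPHB2 (1.78) and WNT10A (1.19) and the TGF-beta targets INHBA (3.35) and PMEPA1 (1.77) were higher in sh51, as were HOXC9 (3.08), CGB3 (2.38), SLC7A11 (2.23) and OXTR (1.501). RASIP1 (-4.50), PSG8 (-3.02), PSG6 (-2.77), RUNX3 (-2.17) and SHISA9 (-1.08) were lower in sh51. The lists of integrins and focal adhesion (median 0.33) and of immediate early and MAPK feedback genes (median 0.35) were higher in sh51, though both calls ended with an estimated correlation and without sh51 replicate 2 (0.34 and 0.43).

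Between the hairpin lines 1394 genes differed, and 18 genes changed in opposite ways against shNT. Of the 1394 genes 686 had passed against shNT with sh49 alone, 152 with sh51 alone, 61 with both the same way, 18 with both in opposite ways and 477 with neither. Unequal loss of the CD63 transcript is argued against by its level, which differed by 0.021 ± 0.18. CD63 protein was not measured, so unequal loss of the protein remains open. Scaling between arrays is argued against by the 1435 genes that differed after quantile normalization. A single aberrant array is argued against as well, since at least 574 genes differed with any of the 4 hairpin arrays left out, the lowest without sh49 replicate 1, and 842, 869, 904 and 854 differed without parental replicate 1, parental replicate 2, shNT replicate 1 and shNT replicate 2. Position on the slide cannot be told apart from the line, because the arrays of each line fill 1 slide column, and differences between the hairpin lines that do not come from CD63, such as other targets of a hairpin, were not tested and remain open.

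The level of CD63 set no array apart, with Dixon ratios of 0.242 among the 4 knockdown arrays and 0.123 among the 4 control arrays, against a critical value of 0.83.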

How the results depend on the processing

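The percentile over detected probes and the array weights were chosen after seeing the data. CD63 stayed past the threshold in the knockdown under 22 of 22 alternatives (-2.60 to -2.31), and CTNNB1 under 0 of 22 (-0.33 to -0.08). Over 153 gene results and 3276 alternatives, direction and side of the threshold held in 2952, the call was lost in 215, gained in 92, reversed in 2 and the sign turned with neither past in 15. Over 65 list results and 1472 alternatives these numbers were 1279, 33, 54, 1 and 105. The reversals came with parental cells as the control, where the cholesterol biosynthesis median was 0.23, SLC7A11 -0.74 and AKR1C1 -0.38. In shNT against parental cells, without a hairpin to CD63, SLC7A11 stood at -1.94, AKR1C1 at -1.27 and the cholesterol median at 0.51. Signal over background limits all comparisons, since under 50% of probes were detected on each array, and 20745 probes were above background on all 8.

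Of the 240 genes changed the same way with both hairpins, 182 stayed with normexp and quantile normalization, 216 with quantile normalization, 186 with median scaling, 193 with the authors' values, 168 with detection on all 8 arrays, 231 with the mean of a gene's probes, 209 with a trended and robust spread, 228 with the percentile over detected probes and 155 with array weights. With the replicate number as a block 199 stayed.

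Without a detection filter 447 genes changed in sh49, 56 in sh51, 177 in the knockdown, 0 in shNT against parental and 377 between the hairpins, with 25 shared by both hairpins, 8 against both controls and 89 in the 4 against 4 comparison. That setting tests more genes (36320) and moved the median of all genes by 0.23 in sh49, 0.16 in the knockdown and -0.21 between the hairpins, and the Wnt target median to 0.046. At adjusted p under 0.01 the counts, in the same order, were 583, 136, 295, 0, 446, 62, 21 and 68, by construction. With only the groups compared, which leaves fewer samples for the spread, they were 137 in sh51, 411 between the hairpins, 90 for both hairpins, 3 against both controls and 1 in shNT against parental. In sh49 more genes changed under that setting, 1062 up and 612 down, against 952 and 544 in the main fit. Array weights gave 279 in sh51, and 1260 up and 781 down in sh49. They also gave 61 against both controls, 40 in shNT against parental and 4774 in the 4 against 4 comparison. Both control lines as the control gave 1339 genes in the knockdown. The 4 against 4 comparison gave 228 genes with the cell line as a random block (consensus correlation 0.134), 233 with the replicate block and 225 with at least a 2-fold change. The 5 genes of shNT against parental became 12 with normexp and quantile normalization, 19 with quantile normalization, 26 with median scaling, 11 with the authors' values, 1 with detection on all 8 arrays, 24 with the mean of a gene's probes, 21 with a trended and robust spread and 10 with the replicate block. With no control array in common 141 genes were shared by both hairpins in the arrangement that moved most, and r across genes was 0.226 and 0.225. Where no cause is given, the cause was not tested.

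Leaving out each array in turn gave 660 to 1689 genes in sh49 (lowest without sh49 replicate 1, highest without sh51 replicate 2), and 702 and 911 without shNT replicates 1 and 2. It gave 290 to 892 in sh51 (without either parental array, without sh51 replicate 2), with 302 without sh49 replicate 1. The knockdown ran from 459 (without shNT replicate 1) to 1313 (without sh51 replicate 2), with 546, 556, 558 and 494 without parental replicates 1 and 2, shNT replicate 2 and sh49 replicate 1. shNT against parental ran from 0 (without either sh49 array) to 199 (without shNT replicate 2), with 153, 65 and 125 without parental replicates 1 and 2 and shNT replicate 1, and 3 and 10 without sh51 replicates 1 and 2. The hairpin difference ran from 574 (without sh49 replicate 1) to 1601 (without sh51 replicate 2), with 842, 869, 904 and 854 without parental replicates 1 and 2 and shNT replicates 1 and 2. Both hairpins shared 111 (without sh49 replicate 1) to 299 (without shNT replicate 2), with 150, 151 and 145 without parental replicates 1 and 2 and sh49 replicate 2. Against both controls it was 27 (without parental replicate 2) to 108 (without sh51 replicate 2), with 46, 28, 30, 42 and 50 without parental replicate 1, shNT replicates 1 and 2 and sh49 replicates 1 and 2. The 4 against 4 count ran from 75 (without shNT replicate 1) to 362 (without sh51 replicate 1), with 116, 84, 84, 143 and 104 without parental replicates 1 and 2, shNT replicate 2 and sh49 replicates 1 and 2. The correlation ran from 0.302 (without sh49 replicate 2) to 0.684 (without shNT replicate 2), with 0.592 without shNT replicate 1. The Wnt target median ran from -0.25 (without sh49 replicate 2, where the list passed) to -0.063 (without sh49 replicate 1), and CD63 from -2.63 to -2.42 in sh49 and from -2.67 to -2.34 in sh51. A lone array of a shared control moves both hairpin effects together.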

Other observations

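The 5 lists of genes in the first paragraphs were chosen after the values of named genes had been seen, and the test of the collagens also after its own result. Their adjusted p is over these 5 lists only, which belong to different comparisons. It is therefore less strict than the adjusted p over the 22 fixed lists, and the values cannot be set side by side. Antigen presentation genes, written down once the interferon list had been seen to rise, were higher in the knockdown as a set. Of 22 genes 19 were measured, 8 rose and none fell. The class II peptide loading genes HLA-DMB and HLA-DMA rose by 2.26 ± 0.19 and 1.55 ± 0.17, the immunoproteasome subunits PSMB9 and PSMB8 by 1.01 ± 0.17 and 0.89, and the class I gene HLA-C by 0.96 ± 0.14, while B2M stood at 0.50 without passing. HLA-C passed with each hairpin (1.07 and 0.84). The other 4 rose in sh49, HLA-DMB by 3.55, HLA-DMA by 2.55, PSMB9 by 1.30 and PSMB8 by 1.08, and did not pass in sh51 (0.97, 0.55, 0.71 and 0.70), and the hairpin lines differed in HLA-DMB (-2.57, adjusted p = 0.00173) and HLA-DMA (adjusted p = 0.00238). The median was 0.67 (adjusted p = 1.19e-12, adjusted p = 0.0130 with an estimated correlation, fry adjusted p = 0.000208), with 0.77 in sh49 and 0.58 in sh51. Before adjustment, camera with an estimated correlation gave p = 0.00261, against p = 0.00558 for the interferon list, which was adjusted over 22 lists. The antigen presentation list was chosen after these data had been seen, so its lower p does not make its rise better supported. Complement genes had 13 of 16 measured and 2 up, CFB with 1.42 ± 0.18 and C1R with 0.94 ± 0.14. Both rose in sh49 (1.88 and 1.76), neither passed in sh51 (0.97 and 0.12), and both differed between the hairpin lines (adjusted p = 0.0461 and 0.00238). Their median was 0.47 (adjusted p = 3.47e-05, adjusted p = 0.0542 with an estimated correlation, fry adjusted p = 0.00484), with 0.92 in sh49 and 0.14 in sh51.

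Collagens other than those that prompted the list had 12 of 19 measured, 4 of them also in fixed lists, and 1 fell. Their median was -0.14 in the knockdown and the list did not pass (adjusted p = 0.0537, adjusted p = 0.203 with an estimated correlation). Of 8 HOXC cluster genes besides HOXC9 only 2 were measured, and both fell in sh49, with a median of -1.59 against 0.22 in sh51. The list passed in sh49 (adjusted p = 0.00169, adjusted p = 0.0928 with an estimated correlation, fry adjusted p = 0.00533), and a list of 2 genes decides little. Cancer-testis antigens had 9 of 31 measured in shNT against parental cells, with none past over all genes, and a median of 0.35 (adjusted p = 7.26e-05, adjusted p = 0.0542 with an estimated correlation, fry adjusted p = 0.0211).

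Both hairpin comparisons use the same shNT arrays, which could by itself give shared genes. With no control array in common, the lower of the ratios to independent lists was still 9.21. Independent lists are a low baseline, because both comparisons take each gene's spread from the same model, so the same genes tend to pass. Still, 141 and 171 genes changed the same way there, against 36 and 40 in opposite ways. They held 110 and 163 of the 240 genes shared against shNT. The shared arrays therefore do not account for the whole overlap, while slide column and line remain joined.

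The 353 genes that separate the 4 hairpin arrays from the 4 control arrays were set against the other splits of the 8 arrays. Of 35 splits 1, the real one, gave as many genes, and the highest of the others gave 2. Only 3 of the splits keep both arrays of every line on the same side, too few for a share under 0.05. The count was 116 and 84 without parental replicates 1 and 2, 75 and 84 without shNT replicates 1 and 2, and 143 and 104 without sh49 replicates 1 and 2.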
